A study of Rattus norvegicus with 12 samples.

How the data were processed

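Gene expression was measured in intestinal mucosa of male Sprague Dawley rats (spelled Spraque Dawley in the labels) on the Illumina RatRef-12 BeadChip, an array of bead-bound probes read by direct hybridization of biotin-labelled cRNA. The labels name both Rat Quad and RatRef-12 BeadChips, and RatRef-12 was taken from the label protocol. Per the labels, 6 rats had a sham operation, in which the bowel was cut and rejoined, and 6 had 75% of the bowel removed, the model of short bowel syndrome (SBS). The 12 arrays came from 3 sham ileal, 4 SBS ileal, 1 sham jejunal and 4 SBS jejunal samples. The labels state that nucleic acid quality limited the number of samples. The time after surgery and the position of each sample along the gut are not given in the sources used here. The sample codes 33 to 39 were read as animal codes, which the labels do not state outright.

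The deposited signal table held the mean bead signal of each probe as an intensity on a linear scale, not normalized between arrays, with a detection p-value (p_value) for each probe and array as deposited. The deposited series matrix held log2 values that the authors had quantile normalized. Its values were the quantile normalization of the log2 signals without background correction, with a largest difference of 5e-06, and its median was 5.86 on each array. The scanner software and its background step are not given in the sources used here. All value columns of both tables were used. Across the 12 arrays, 7041 to 8821 of 22517 probes were detected at p under 0.05, and median signals ran from 52.1 to 62.5. The number of arrays per group limits the precision.

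Signals were background corrected with the normexp model, with the background estimated from the detection p-values (neqc, offset 16), quantile normalized and put on a log2 scale with limma 3.58.1 in R 4.3.3. Probes detected at p under 0.05 on at least 3 of the 12 arrays were kept, which left 9137 probes, of which 6811 carried a gene symbol and stood for 6702 genes. Gene symbols came from the array annotation, joined to current names by Entrez identifier for 13747 probes and by accession alone for 5, and 4 symbols were updated; 8730 probes carried no symbol. No genome positions were used.

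A linear model with 1 mean per group over all 12 arrays was fitted with limma (lmFit and eBayes), with 1 shared spread per probe. The comparisons were SBS against sham in ileum, SBS against sham in jejunum, the difference of these effects (jejunum minus ileum), and jejunum against ileum in SBS rats. The lone sham jejunal array was assumed to vary like the arrays of the other groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over 9137 probes, and probes with adjusted p under 0.05 were called. Counts are of probes. Log2 differences are given with standard errors (SE) of the model and group levels with standard deviations (SD). Where a probe was undetected on all arrays of the lower group, a lower bound of the fold was computed from the lowest detected value; these bounds hold for the background correction used, and differences without it can lie below them. Where the lower group was detected on some of its arrays only, its level rests in part on the background. Fixed gene lists, 32 in number, of pathways and of cell types that mucosa can hold, were tested with camera (preset correlation 0.01, at least 4 measured genes, 1 probe per gene with the highest mean signal), with an estimated correlation and with fry beside it; 27 lists were large enough. In a test on simulated data, 100 probes were changed at each size, with values drawn independently for each probe and array. A log2 change of 1 was found for 70% of probes in ileum, 42% in jejunum, 81% between regions and 26% for the difference of effects. A log2 change of 2 was found for 92%, 88%, 94% and 82%. Variation that probes share on an array was left out of the simulation, which limits how far these rates carry over.

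The genes to name were fixed by rule before the data were examined, as were the lists, the model and most alternatives: up to 8 called genes per direction with the largest log2 difference and no overlap between the values of the groups compared, the measured genes of the platelet-derived growth factor (PDGF) list, and up to 4 genes per list by the size of the moderated statistic. For lists that were not called, members are named where they passed adjusted p under 0.05. For the difference of effects, overlap of values is undefined and was not asked for, and members of lists that did not pass are not named. Some of the named genes are left to counts for brevity.

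With the codes read as animal codes, samples of SBS ileum and SBS jejunum with the same code came from the same rat. The deviations of their arrays from the group means correlated by 0.66, 0.47, 0.19 and 0.44 across probes. Alternatives were other background corrections, median scaling and cyclic loess in place of quantile normalization, the deposited series matrix, no filter and a stricter filter (p under 0.01 on all arrays of a group), array weights, the animal as a random block (statmod 1.5.0), the replicate number as a fixed block, fits on fewer arrays, the mean over the probes of a gene, a prior variance with trend, and each array left out in turn. The fit with a random block used the preranked form of camera for the lists. After the data were seen, a fit without both arrays of rat 36 and the alternatives for the lists on region and on the difference of effects were added. Chip positions are not given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.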

Results

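Expression was compared between sham-operated and resected rats in mucosa of ileum (3 sham and 4 SBS arrays) and of jejunum (1 sham and 4 SBS arrays). Of 22517 probes, 8119 to 8695 were detected on the sham ileal arrays, 7514 to 8415 on the SBS ileal arrays, 8095 on the sham jejunal array and 7041 to 8821 on the SBS jejunal arrays. Median signal intensities were 59.4 to 62.1, 52.7 to 62.5, 57.4 and 52.1 to 60.7 in the same order. The first principal component of the kept probes held 45.5% of the variance and ran from sham ileum (-36.79 to -26.75) over SBS ileum (-20.57 to 4.89) and the sham jejunal array (0.99) to SBS jejunum (18.84 to 47.54), so that it followed region and resection together.

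Resection in ileum was followed by lower transcript levels of Plb1, the brush border phospholipase B, from a log2 level of 10.31 ± 0.25 (SD, n = 3) to 4.86 ± 0.68 (SD, n = 4), near background (adjusted p = 4.2e-06 in limma). Clu, the secreted chaperone clusterin, fell by 2.97 ± 0.31 (SE) on the log2 scale (adjusted p = 0.00149). On SBS ileum 1 and 4 it lay below the lowest detected value, so its level there rests on the background. Acta1, the actin of skeletal muscle, rose 42.6-fold from 6.57 ± 0.96 (SD, n = 3) to 11.98 ± 1.43 (SD, n = 4; adjusted p = 0.0046). The other skeletal muscle genes on the array, 13 in number with 9 detected on 0 arrays, had a median log2 difference of 0.00128. Gcg, which encodes proglucagon, the precursor of the glucagon-like peptides, rose 2.81-fold, by 1.49 ± 0.16 (SE) on the log2 scale (adjusted p = 0.00151). The plasminogen activator Plat rose 5.50-fold (adjusted p = 0.0243), and the carbonic anhydrase genes Car13 (log2 difference 1.35, adjusted p = 0.00921) and Car1 (at least 2.07-fold with this background correction, adjusted p = 0.0304) rose as well. In the series matrix, which has no background correction, Car1 differed by 0.73 on the log2 scale, below that bound. Prr15, Lap3 and Vkorc1l1 rose by 1.39, 1.43 and 1.37 on the log2 scale (adjusted p = 0.0085, 0.0413 and 0.0411).

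All 3 measured genes of the B and plasma cell list fell in resected ileum, and all 3 fell when adjusted over the list alone. Ms4a1, a B cell surface protein, fell by 2.17 ± 0.28 (SE) on the log2 scale (adjusted p = 0.00391), Cd79b, a part of the B cell receptor, fell by 2.23 ± 0.30 (adjusted p = 0.0046), and the complement receptor gene Cr2 fell by 1.21 ± 0.19 (adjusted p = 0.0085). Cxcl13, the chemokine that draws B cells into follicles, fell by 3.69 (adjusted p = 0.0066). These 4 genes varied together over the 7 ileal arrays within groups, with a mean correlation of 0.904. The 12 measured T and NK cell genes had a median log2 difference of -0.00021, with 6 positive and 6 negative differences, and none passed. Mfge8, Enpp2, Prkcb, Cd83 and Apoe fell, with log2 differences of -3.13, -2.65, -2.56, -2.49 and -2.43 (adjusted p = 0.0117, 0.0182, 0.0125, 0.0138 and 0.00753). Like Cxcl13, these genes and Clu were lowest on sham ileum 1 among the sham ileal arrays and highest on SBS ileum 2 among the SBS ones. The B and plasma cell list was too small for the list test. The differences of Ms4a1, Cd79b, Cr2 and Apoe were -1.35, -1.46, -0.66 and -1.60 with the series matrix. Ms4a1, Cr2 and Apoe lay below the lowest detected value on SBS ileum 1, 3 and 4, Cxcl13 and Enpp2 on SBS ileum 1 and 4, and Cd79b on SBS ileum 1. Their SBS levels rest in part on the background.

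In all, 269 probes changed in resected ileum, 60 higher and 209 lower, and 140 of them by over 2-fold. With median scaling 21 were higher and 212 lower. The count of 269 became 26 without sham ileum 2, 26 without sham ileum 3, 123 without SBS ileum 1 and 163 without SBS ileum 4. It was 171 with no filter on dim probes, 930 with array weights and, in a fit chosen after seeing the data, 140 without rat 36. Of 23 named genes that passed, Plb1, Clu, Acta1, Gcg, Ms4a1 and Cd79b passed in each of the fits with 1 array left out. The other 17 genes did not pass without sham ileum 2 (adjusted p = 0.0503 to 0.156) nor without sham ileum 3 (adjusted p = 0.0552 to 0.236). Fewer lost their call without SBS ileum 1 (7 genes, adjusted p = 0.0538 to 0.119), SBS ileum 3 (6 genes, 0.057 to 0.0937), SBS ileum 2 (4 genes, 0.0501 to 0.0636) and SBS jejunum 3 (3 genes, 0.0517 to 0.0653). With no filter 10 genes lost their call (Car1, Cd83, Enpp2, Icam1, Lap3, Mfge8, Plat, Prkcb, Stard4 and Vkorc1l1; adjusted p = 0.0555 to 0.127), and with the ileal arrays alone 5 of these did (Car1, Icam1, Lap3, Stard4 and Vkorc1l1; 0.0602 to 0.0708). Lap3, Vkorc1l1 and Icam1 lost it with the series matrix (0.0523 to 0.0627), and Lap3, Vkorc1l1, Nsdhl and Stard4 with median scaling (0.0564 to 0.166). Without rat 36, 6 genes lost it (0.0555 to 0.0908). Clu differed by -1.89 with an offset of 50 in the background correction. Without SBS ileum 4, SBS jejunum 2 or sham ileum 1, 2 genes each lost it (0.0602 to 0.0695, 0.0522 to 0.0609 and 0.0784 to 0.0792).

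Among the fixed gene lists, cholesterol synthesis was higher in resected ileum with the preset correlation (adjusted p = 4.44e-05) but not with an estimated one (adjusted p = 0.679 with an estimated correlation). Of its 10 measured genes, 2 rose and 8 did not pass, 7 rose when adjusted over the list alone, and all 10 log2 differences were positive with a median of 0.63. Nsdhl, a sterol dehydrogenase, rose by 0.97 ± 0.17 (SE) on the log2 scale (adjusted p = 0.0116), and the sterol carrier Stard4 rose by 0.80 (adjusted p = 0.0354); Idi1 differed by 0.89 (adjusted p = 0.0755). Oxidative phosphorylation had 15 positive differences among 15 genes, with a median of 0.26 (adjusted p = 0.000418, and adjusted p = 0.679 with an estimated correlation); 0 rose, and 2 rose when adjusted over the list alone. Its Ndufs1 and Sdhb, of the respiratory chain, differed by 0.70 and 0.66 (adjusted p = 0.0639 and 0.0977).

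Tuft cell genes were lower in resected ileum, with a median of -0.56 over 5 measured genes (adjusted p = 0.00664, adjusted p = 0.244 with an estimated correlation and 0.000487 in fry). Pou2f3, a transcription factor of tuft cells, fell by 0.69 on the log2 scale (adjusted p = 0.0107) and 4 genes did not pass, among them Hpgds (-0.73, adjusted p = 0.0652); 3 fell when adjusted over the list alone. With the series matrix the tuft cell median was -0.29 and the Pou2f3 difference -0.36. Pou2f3 lay below the lowest detected value on SBS ileum 1, 3 and 4. Of 27 ribosomal protein genes 22 had negative differences (median -0.37), 0 passed, and 0 passed when adjusted over the list alone (adjusted p = 0.00664, and adjusted p = 0.898 with an estimated correlation). Rpl30 differed by -0.64 (adjusted p = 0.116). The ribosomal list lost its call without sham ileum 3 (adjusted p = 0.0536), SBS ileum 1 (0.0771, median -0.22) or SBS ileum 3 (0.0827, median -0.24), and with median scaling (0.113). Of 21 cell cycle genes 19 had negative differences (median -0.24), 0 passed, and 1 fell when adjusted over the list alone (adjusted p = 0.0421, and adjusted p = 0.93 with an estimated correlation). The replication factor gene Mcm3 differed by -1.09 (adjusted p = 0.0565). The cell cycle list was not called in 9 of 13 other settings, nor without sham ileum 2 (adjusted p = 0.0656), sham ileum 3 (0.103), SBS ileum 1 (0.624) or SBS ileum 3 (0.11). The cell cycle median was -0.0087 without SBS ileum 1, -0.37 without SBS ileum 2, -0.42 without SBS ileum 4 and -0.01 without rat 36. With 5 lists called in camera, 0 held with an estimated correlation and 1 was called in fry, and 20 of 35 splits of the 7 ileal arrays gave at least 5. In the inflammation list Icam1, a leukocyte adhesion molecule, fell by 0.88 (adjusted p = 0.0264), 1 of 13 measured genes, but differed by -0.46 and did not pass with the series matrix (adjusted p = 0.0523).

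**Figure D1:**
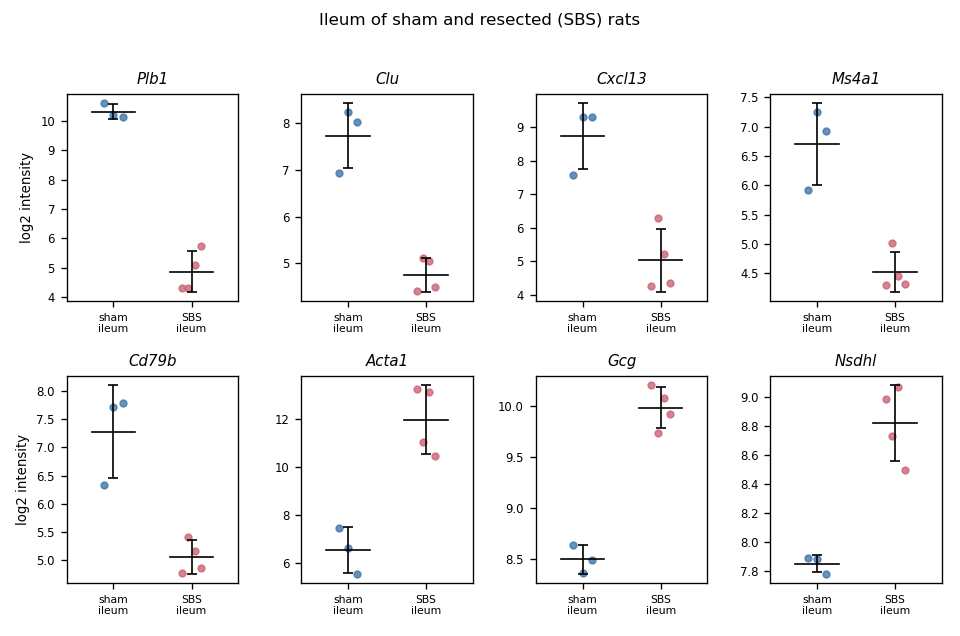
Log2 intensity (vertical axes) of 8 genes on 3 sham and 4 SBS ileal arrays (points), with the mean and SD (bars). Plb1, Clu, Cxcl13, Ms4a1 and Cd79b lay lower on the SBS arrays, and Acta1, Gcg and Nsdhl lay higher.

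The series asked how resection affects genes related to PDGF. Of 7 listed ligand and receptor genes 6 were on the array and 2 were measured: Pdgfa, the A chain of the growth factor, was detected on 12 arrays and Pdgfra, its alpha receptor, on 4. Pdgfc was detected on 2 arrays and Pdgfb, Pdgfd and Pdgfrl on 0. In ileum the Pdgfa level was 8.89 ± 0.40 (SD, n = 3) in sham and 8.77 ± 0.37 (SD, n = 4) in SBS rats, a log2 difference of -0.12 ± 0.25 (SE; adjusted p = 0.862). It was 0.09 without sham ileum 1 and 0.01 without SBS ileum 2. Pdgfra differed by -0.13 ± 0.16 (SE; adjusted p = 0.732). In jejunum Pdgfa stood at 9.51 on the sham array and 8.74 ± 0.35 (SD, n = 4) on the SBS arrays, a difference of -0.77 ± 0.37 (SE; adjusted p = 0.448). Pdgfra differed there by -0.60 ± 0.23 (SE; adjusted p = 0.299), and 1 gene fell when adjusted over the list alone. Neither gene passed in either region, and the resection effects on Pdgfa differed between regions by -0.65 (adjusted p = 1 in limma). The median over both genes was -0.12 in ileum and -0.68 in jejunum, with camera p of 0.487 and 0.0232, and p = 0.506 and 0.0525 with an estimated correlation. Without sham ileum 1 the ileal median was 0.04. The jejunal median was -0.04 with no filter and -0.57 with the animal as a random block, and with 2 measured genes the list was too small to be called. Of 16 measured genes that relay PDGF signals, 0 passed in ileum (median 0.10, adjusted p = 0.749) and 0 in jejunum (median 0.03, adjusted p = 0.959), and 1 and 0 rose when adjusted over the list alone.

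**Figure D2:**
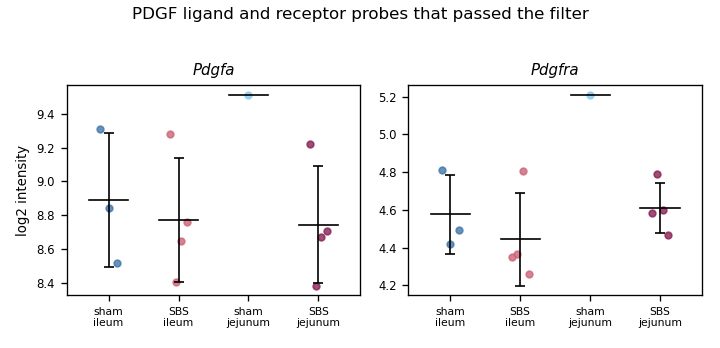
Log2 intensity (vertical axes) of Pdgfa and Pdgfra on the arrays of each group (points), with the mean and SD (bars); the 1 sham jejunal array has a line at its value and no SD. Neither gene passed in ileum or jejunum.

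In jejunum Plb1 was at least 179-fold lower after resection (12.26 on the sham array, 4.30 ± 0.03, SD, n = 4, on the SBS arrays; adjusted p = 4.34e-06). Fam151a fell by 5.81 ± 0.34 (SE) on the log2 scale (adjusted p = 5.26e-06), to levels detected on 2 of 4 SBS jejunal arrays, and Cmahp fell 58.9-fold (adjusted p = 0.000366). Cubn, the receptor for vitamin and protein uptake cubilin, fell from 9.66 to near background, detected on 1 of 4 SBS jejunal arrays (adjusted p = 0.00673). The monocarboxylate transporter gene Slc5a12 fell 16.6-fold on its probe with the highest signal (adjusted p = 0.0163). The mean over its probes differed by -1.91 on the log2 scale, against -4.06 for that probe. Its probes thus disagreed, and the rest fell less or not at all. Spink4, a goblet cell peptide, rose 24.9-fold from 8.62 to 13.26 ± 0.42 (SD, n = 4; adjusted p = 0.000427). Slc11a2, which imports iron, rose 12.1-fold (adjusted p = 0.000825) and Slc40a1, the iron exporter ferroportin, rose 17.3-fold (adjusted p = 0.0445). They were the 2 of 15 measured genes of sugar, amino acid and ion transport that rose; 1 fell, 13 differences were negative, and the list, with a median of -0.63 and a mean of -0.09, was not called (adjusted p = 0.0794). The calcium-binding protein gene S100g rose 15.9-fold (adjusted p = 0.0499), the trefoil factor Tff2 at least 18.4-fold (adjusted p = 0.0109) and Ugt2b7 at least 19.6-fold (adjusted p = 0.0227). Reg4 rose 11.5-fold (adjusted p = 0.0211) and Plet1 at least 16.1-fold (adjusted p = 0.0122). These bounds hold with this background correction only, and the differences of Plb1, Tff2, Ugt2b7 and Plet1 in the series matrix were short of them. Gcg fell by 2.02 ± 0.23 (SE) on the log2 scale, from 8.69 to 6.67 ± 0.23 (SD, n = 4; adjusted p = 0.00193). The array SBS jejunum 1, of rat 36, held pancreatic transcripts, with Pnlip at 9.12 against at most 5.30 on the other 11 arrays.

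Of 16 measured genes of the interferon and antigen presentation list, 5 fell in resected jejunum and 11 did not pass, 7 fell when adjusted over the list alone, and the median was -1.10 (adjusted p = 1.26e-09, adjusted p = 0.19 with an estimated correlation and 0.0145 in fry). The class II genes Cd74 (-2.19 ± 0.28, SE, adjusted p = 0.00346), RT1-Ba (6.67-fold lower, adjusted p = 0.0122), RT1-Da (-1.90, adjusted p = 0.0116) and RT1-Db1 (-1.99, adjusted p = 0.0169) fell. The 3 measured B and plasma cell genes had a median of -1.57 in jejunum, with 0 past the test over all probes and 3 fallen when adjusted over the list alone. Cholesterol synthesis had a median of 1.20 over 10 genes; 1 rose, the squalene synthase gene Fdft1 (1.65, adjusted p = 0.0402), and 8 rose when adjusted over the list alone. The cholesterol list gave adjusted p = 1.35e-08, adjusted p = 0.267 with an estimated correlation and 0.0384 in fry. Among 13 brush border genes 2 fell, the lactase gene Lct at -2.20 (adjusted p = 0.0239) and the peptidase gene Enpep at -2.21 (adjusted p = 0.0478), and 3 fell when adjusted over the list alone (median -0.27, adjusted p = 0.012, and adjusted p = 0.713 with an estimated correlation). T and NK cell genes had a median of -0.88 over 12 genes; 0 passed and 4 fell when adjusted over the list alone (adjusted p = 0.00268, and adjusted p = 0.713 with an estimated correlation). Cd247, a T cell receptor chain, differed by -1.36 (adjusted p = 0.081). Tuft cell genes had a median of -0.57 over 5 genes; Pou2f3 fell at least 1.29-fold (adjusted p = 0.0427) and 2 fell when adjusted over the list alone (adjusted p = 0.012, adjusted p = 0.19 with an estimated correlation, 0.00318 in fry). All 15 oxidative phosphorylation genes had positive differences (median 0.23); 0 passed and 1 rose when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.713 with an estimated correlation). In lists that were not called, Timp1, Hmox1 and Gstp1 rose by 1.81, 2.13 and 1.89 (adjusted p = 0.0214, 0.0239 and 0.0209), and Slc1a1, Igfbp3 and Guca2a fell, at -1.57, -1.23 and -1.98 (adjusted p = 0.0227, 0.0395 and 0.0452). With the series matrix the medians were -0.73 for interferon and antigen presentation, -0.58 for T and NK cells and -0.37 for tuft cells, and the differences of Enpep, Igfbp3 and Pou2f3 were -1.45, -0.65 and -0.54. With an offset of 50 in the background correction, the cholesterol median was 0.78 and the Lct difference -1.43. The brush border median was -0.11 with median scaling, -0.44, -0.17, -0.41 and -0.15 without SBS jejunum 1, 2, 3 and 4.

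In jejunum 134 probes changed, 58 higher and 76 lower, and 126 of them by over 2-fold. All of these contrasts rested on 1 sham array, and a fit on the 5 jejunal arrays alone called 21 probes, 13 of them shared. Over probes chosen to differ between SBS ileum and SBS jejunum, that array lay between them. Its median positions were 0.392 to 0.677 on an axis from the former (0) to the latter (1). An effect of resection in jejunum was therefore not separated from a sham sample taken nearer the ileum. In the fit on jejunal arrays alone 22 of 30 named genes lost their call (adjusted p = 0.073 to 0.251), among them Gcg, Cd74, RT1-Da, Tff2, Ugt2b7, Reg4 and Lct, while Plb1, Spink4, Slc11a2, Slc40a1, Cmahp, Fam151a, Cubn and RT1-Ba passed. With no filter 19 of 30 lost it (0.0525 to 0.178), RT1-Ba, Slc40a1 and Slc5a12 among them, with median scaling 9 (0.0598 to 0.165), with cyclic loess 7 (0.0503 to 0.0627) and with the series matrix 6 (0.0508 to 0.114). Enpep, Fdft1 and S100g lost it with the animal as a random block (0.07, 0.0526 and 0.0718), S100g also with the mean over its probes (0.0509), and 5 genes without rat 36 (0.0576 to 0.0756). The count was 80 with median scaling (50 higher and 30 lower), 72 with no filter and 244 with array weights. Of 30 named genes that passed, Lct lost its call without SBS jejunum 3 (adjusted p = 0.0516), and Slc40a1, S100g, Enpep, Fdft1, Guca2a, Igfbp3 and Pou2f3 lost it in 5 to 9 of the fits with 1 array left out. The lost calls had adjusted p from 0.0537 to 0.0681 without SBS jejunum 1, 0.0693 to 0.104 without SBS jejunum 2, 0.0515 to 0.0862 without SBS jejunum 3 and 0.0507 to 0.0581 without SBS jejunum 4. They had 0.0553 to 0.0627, 0.0515 to 0.061, 0.0599 to 0.0716 and 0.0554 to 0.0624 without SBS ileum 1, 2, 3 and 4, and 0.0549 to 0.0609, 0.0671 to 0.0787 and 0.0552 to 0.0695 without sham ileum 1, 2 and 3. The brush border list was not called in the fit on jejunal arrays alone (adjusted p = 0.0526). With 6 lists called in camera, 0 held with an estimated correlation and 3 were called in fry.

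Of the probes called in ileum and in jejunum 35 were shared, 24 of them named, and 34 changed in the same direction. Plb1, Clu, Pou2f3 and the B cell gene Cd72 were among 30 that were lower in both, against 1.74 for independent sets, and Pecr and Prss32 were among 4 that were higher in both, against 0.38. Gcg was the 1 gene with opposite directions. Across probes, which are not independent, the log2 differences of both regions correlated by 0.50. The regions shared no arrays, but by their codes the samples came from the same rats, and both tests used the same spread for each probe. The excess over independent sets is therefore not a measure of a shared effect alone.

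The difference of resection effects between jejunum and ileum was tested directly. Gcg rose in ileum and fell in jejunum, a difference of -3.51 ± 0.28 (SE, log2; adjusted p = 0.00018). Fam151a (-5.80 ± 0.41, adjusted p = 9.08e-05), Cubn (-6.44 ± 0.85, adjusted p = 0.00898) and Cmahp (-5.03, adjusted p = 0.00898) had lower effects in jejunum, as did Slc5a12 (-4.89, adjusted p = 0.0499; -2.41 for the mean over its probes). Fam151a was detected on 1 of 3 sham and 1 of 4 SBS ileal arrays, so that a fall there could hardly be measured. Cubn was detected on 1 of 4 SBS jejunal arrays, so that its value rests in part on the background. Tlcd4 and Slit1 passed too, but lay at background on all 3 sham ileal arrays, so that their difference of effects was set by the background and is not read as one. Spink4 (3.91 ± 0.52), Slc11a2 (3.40) and the calcium pump gene Atp2b1 (2.36 ± 0.30) had higher effects in jejunum (adjusted p = 0.00898 for each). So had Wfdc21 (3.31, adjusted p = 0.0241), Htatip2 (2.70, adjusted p = 0.0314), Fntb (2.07, adjusted p = 0.0231) and Bok (1.97, adjusted p = 0.0351). Fntb was undetected on the sham jejunal array. With the series matrix Fntb had 1.17, and with an offset of 50 Wfdc21 had 2.16 and Bok 1.30. In all 18 probes passed, 9 in each direction. The lone sham jejunal array limits these differences too. Its position between SBS ileum and SBS jejunum was a median over other probes, chosen to differ between those regions. On it, Fam151a (10.67), Cubn (9.66) and Cmahp (11.69) stood above all SBS arrays, and Slc11a2 (6.64) and Spink4 (8.62) below them. That position does not describe these genes, while Gcg, Slc5a12, Atp2b1 and Wfdc21 lay within the range of the SBS arrays.

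Interferon and antigen presentation had a lower effect in jejunum (16 genes, median -0.67, adjusted p = 8.56e-10; adjusted p = 0.241 with an estimated correlation), with 0 genes past the test and 5 lower when adjusted over the list alone. T and NK cells (median -0.79, adjusted p = 0.00139; adjusted p = 0.69 with an estimated correlation) had 0 and 1, and the brush border (median -0.35, adjusted p = 0.00277; adjusted p = 0.69 with an estimated correlation) had 0 and 2. Sugar, amino acid and ion transport had a median of -0.90 (adjusted p = 0.00558; adjusted p = 0.69 with an estimated correlation) although Slc11a2, which passed, went the other way, and 2 were higher and 1 lower when adjusted over the list alone. Lipid absorption (median -0.39, adjusted p = 0.0459; adjusted p = 0.893 with an estimated correlation) had 0 and 0, and trophic factors (median -0.27, adjusted p = 0.0459; adjusted p = 0.69 with an estimated correlation) had Gcg, which stayed when adjusted over the list alone. Cholesterol synthesis was higher (median 0.39, adjusted p = 0.0194; adjusted p = 0.857 with an estimated correlation), with 0 and 0. Fry called 0 of these 7 lists. With the series matrix cholesterol synthesis (median 0.15, adjusted p = 0.116) and trophic factors (median -0.16, adjusted p = 0.0824) were not called, nor with an offset of 50 (adjusted p = 0.136 and 0.081) or array weights (0.058 and 0.0706). Lipid absorption was not called with array weights (0.129), cyclic loess (0.0726), no filter (0.162) or the stricter filter (0.0864), nor without rat 36 (0.0996). Trophic factors were not called with no filter (0.162) or the stricter filter (0.167). The T and NK median was -0.42 with the series matrix, and with median scaling the medians were -0.44 for interferon and antigen presentation, -0.15 for the brush border and -0.25 for lipid absorption. The brush border median was -0.22 without SBS ileum 1, the lipid median -0.26 without sham ileum 3 and the cholesterol median 0.60 without SBS ileum 3 and 0.23 without SBS ileum 4. As by their codes both regions came from the same rats, the animal was fitted as a random block, and lipid absorption was then not called (adjusted p = 0.0953).

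The 18 probes rested on the lone sham jejunal array. Their number was 28 without sham ileum 1, 8 without sham ileum 2, 9 without sham ileum 3, 9 without SBS ileum 2, 9 without SBS ileum 3 and 28 without SBS jejunum 4, 51 with array weights and 36 with the animal as a random block. Gcg, Fam151a, Cubn, Cmahp, Spink4, Slc11a2 and Atp2b1 passed in each fit with 1 array left out. With no filter 7 of the 14 named genes lost their call, Cubn (0.0664) and Spink4 (0.0584) among them, up to 0.215 for Slc5a12. Wfdc21, Htatip2 and Fntb lost it with the series matrix (0.0567 to 0.0692), Bok and Slc5a12 with median scaling (0.0757 and 0.114), and Slc5a12 with cyclic loess (0.0532) and the mean over its probes (0.101). Bok, Slc5a12 and Slit1 lost it without rat 36 (0.0511 to 0.0798). The other 7 named genes lost their call without sham ileum 2 (adjusted p = 0.0595 to 0.125), and some of them without sham ileum 3 (6 genes, 0.0615 to 0.133), sham ileum 1 (2 genes, 0.0669), SBS ileum 1 (3 genes, 0.0656 to 0.0956), SBS ileum 2 (6 genes, 0.0638 to 0.107), SBS ileum 3 (6 genes, 0.0546 to 0.135) or SBS ileum 4 (5 genes, 0.0501 to 0.0739). SBS jejunum 2 (2 genes, 0.0812) and SBS jejunum 3 (2 genes, 0.0643 to 0.114) ended calls too. Of the lists, lipid absorption, trophic factors and cholesterol synthesis lost their call without some arrays: sham ileum 2 (0.0716), sham ileum 3 (0.0638 to 0.188), SBS ileum 1 (0.203), SBS ileum 3 (0.0996 to 0.103), SBS ileum 4 (0.102), SBS jejunum 2 (0.0581 to 0.0998) and SBS jejunum 4 (0.121 to 0.199).

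**Figure D3:**
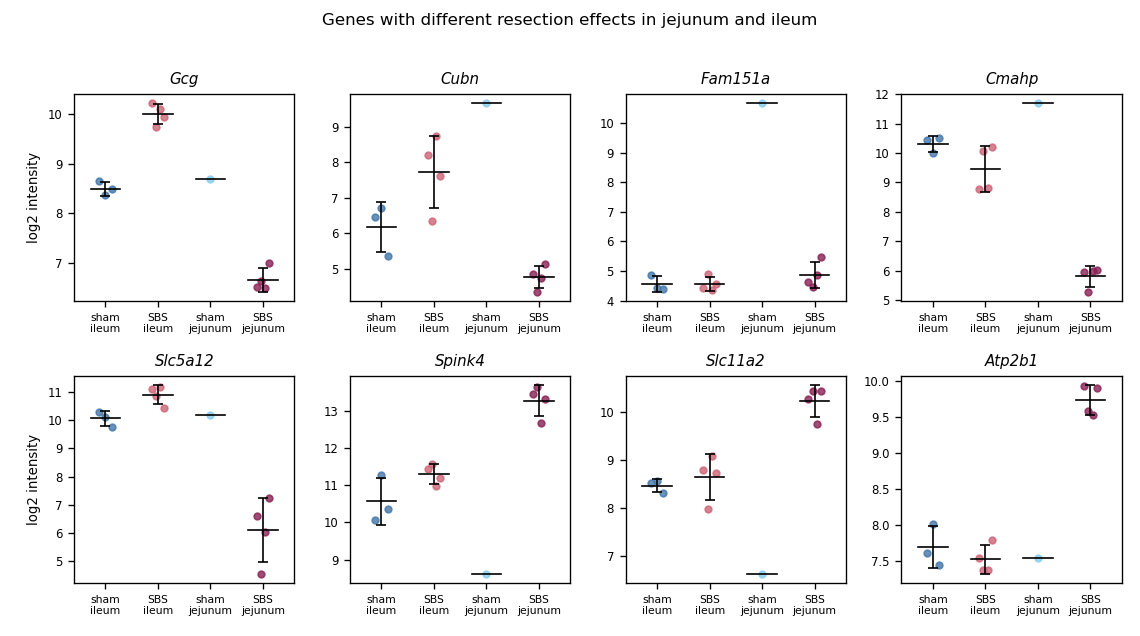
Log2 intensity (vertical axes) of 8 genes with different resection effects on the arrays of each group (points), with the mean and SD (bars); the 1 sham jejunal array has a line at its value and no SD. Gcg lay higher in SBS than in sham ileum and lower in SBS than in sham jejunum; Fam151a lay near background in ileum.

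In SBS rats genes of ileal bile acid handling were lower in jejunum than in ileum: of 7 measured genes 6 fell, 6 when adjusted over the list alone, and the median was -1.68 (adjusted p = 2.11e-08, and adjusted p = 0.114 with an estimated correlation). Slc10a2, the bile acid importer, fell by 2.38 (adjusted p = 1.39e-05), the exporter gene Slc51b fell by 2.62 (adjusted p = 3.59e-05) and Nr1h4, the bile acid receptor, fell by 1.19 (adjusted p = 0.000101). Fabp6, the ileal bile acid binding protein, was lower (14.27 ± 0.11 in ileum and 8.21 ± 3.61 in jejunum, SD, n = 4 each; adjusted p = 0.0115). No fold is given, since its ileal values lay at the top of the scale, which limits the log2 difference of -6.06. It was -7.91 without SBS jejunum 4, on which Fabp6 stood at 13.56, and -5.28 without rat 36. Pyy, a hormone of the distal gut, fell by 3.58 ± 0.27 (SE; adjusted p = 1.68e-05) and Gcg fell by 3.32 ± 0.15 (SE; adjusted p = 3.69e-07), while Gip, the hormone of the proximal gut, was at least 5.77-fold higher with this background correction (adjusted p = 3.69e-07). Its log2 difference in the series matrix was 1.74, short of that bound. Alpi, the intestinal alkaline phosphatase, rose 50.1-fold from 7.38 ± 2.13 to 13.02 ± 0.72 (SD, n = 4 each; adjusted p = 0.00434), Enpp3 33.8-fold (adjusted p = 0.00239) and Slc40a1 15.1-fold (adjusted p = 0.000922). Hoxb7, a position gene of the trunk, was at least 16.9-fold lower (adjusted p = 0.000734), likewise with this background correction only, and Tmigd1 (28.2-fold) and Slc5a12 (27.5-fold) were lower too (adjusted p = 0.000236 and 4.92e-05), with -2.33 on the log2 scale for the mean over the probes of Slc5a12. The 27.5-fold change of Slc5a12 holds for its probe with the highest signal only. With the series matrix the differences were -1.45 for Slc10a2 and -0.68 for Nr1h4, and with an offset of 50 that of Pyy was -2.36.

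T and NK cell genes were lower in SBS jejunum than in SBS ileum (adjusted p = 5.46e-06, and adjusted p = 0.336 with an estimated correlation). Of 12 measured genes 8 fell, 9 when adjusted over the list alone, and the median was -1.06, with Cd8a at -1.84 and the granzyme gene Gzma at -2.19 (adjusted p = 0.00182). Of 16 interferon and antigen presentation genes 8 fell, 10 when adjusted over the list alone (median -0.77, adjusted p = 3.45e-07, and adjusted p = 0.19 with an estimated correlation), with Cd74 at -2.33 (adjusted p = 1.68e-05). Xenobiotic metabolism was higher: of 19 genes 10 rose and 1 fell, 12 and 2 when adjusted over the list alone (median 1.05, adjusted p = 2.82e-06, and adjusted p = 0.181 with an estimated correlation), with Gsta3 at 2.34 (adjusted p = 6.66e-05) and the exporter gene Abcg2 at -1.59. Oxidative phosphorylation had 7 of 15 genes higher, 9 when adjusted over the list alone (median 0.41, adjusted p = 3.45e-07, and adjusted p = 0.211 with an estimated correlation), with Ndufv1 at 1.00 (adjusted p = 0.000381). Lipid absorption had 4 of 12 higher, 5 when adjusted over the list alone (median 0.63, adjusted p = 5.29e-05, and adjusted p = 0.387 with an estimated correlation), with the fatty acid transporter gene Cd36 at 1.51. Cholesterol synthesis had 3 of 10 lower, 7 when adjusted over the list alone (median -0.65, adjusted p = 0.000224, and adjusted p = 0.407 with an estimated correlation), with Fdft1 at -1.09. With median scaling these 3 genes, Fdft1, Dhcr7 and Nsdhl, did not pass (adjusted p = 0.0558, 0.127 and 0.189 in limma). Nsdhl did not pass without rat 36 either (adjusted p = 0.063 in limma). With the series matrix the medians were -0.61 for T and NK cells, -0.46 for interferon and antigen presentation and 0.67 for xenobiotic metabolism, and Cd36 differed by 1.00; with no filter the interferon median was -0.28.

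Of the 7 lists called in camera, 0 held with an estimated correlation. Fry called 10 lists, and 8 of 35 splits of the 8 SBS arrays gave at least 7 lists. In all 849 probes differed between the regions, 448 higher and 401 lower in jejunum, and 358 of them by over 2-fold. With the animal as a random block 1519 probes were called, and with median scaling 726, of which 492 were higher and 234 lower. Fabp6 did not pass without rat 36 (adjusted p = 0.0503), nor with no filter (adjusted p = 0.0598). On the jejunal array of rat 36 it stood at 5.96, near SBS jejunum 2 and 3 (6.15 and 7.15). Without SBS jejunum 4, where it stood at 13.56, it passed (adjusted p = 1.57e-08 in limma). Of 8 measured goblet cell genes 1 rose, Spink4 by 1.97, and 3 fell, with Guca2a at -1.66, Clca1 at -1.17 and Clca4 at -0.88, and the list was not called (adjusted p = 0.778). Neither Clca1 nor Clca4 passed with median scaling or with no filter. With 1 array left out, Clca1 did not pass in 4 fits (adjusted p = 0.0554 to 0.0823 in limma) and Clca4 in 5 (0.05425 to 0.0845). Pdgfa differed by -0.03 between regions (adjusted p = 0.968), and by 0.14 with median scaling and 0.06 with cyclic loess.

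**Figure D4:**
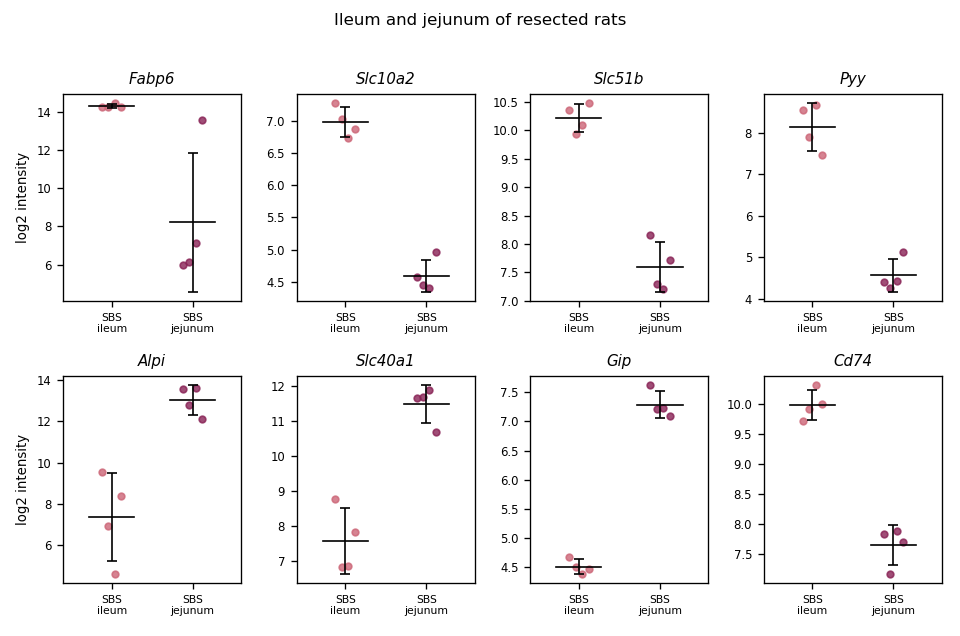
Log2 intensity (vertical axes) of 8 genes on 4 SBS ileal and 4 SBS jejunal arrays (points), with the mean and SD (bars). Fabp6, Slc10a2, Slc51b, Pyy and Cd74 lay lower in jejunum, with Fabp6 at 13.56 on SBS jejunum 4 close to its ileal values, and Alpi, Slc40a1 and Gip lay higher.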

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

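The test of the sham jejunal array's position and the fit without rat 36 were chosen after the result was seen. The resection effect differed between jejunum and ileum for 14 named genes, with log2 differences of effects of 3.91 for Spink4, 3.40 for Slc11a2, 3.31 for Wfdc21, 2.70 for Htatip2, 2.36 for Atp2b1, 2.07 for Fntb, 1.97 for Bok, -6.44 for Cubn, -5.80 for Fam151a, -5.03 for Cmahp, -4.89 for Slc5a12, -3.51 for Gcg, -1.74 for Tlcd4 and -1.40 for Slit1. Tlcd4 and Slit1 lay at background in sham ileum, Fam151a near it in both ileal groups and Cubn near it in SBS jejunum, so that the background limits what these 4 values show. It also differed for 7 gene lists, with medians of -0.35 for brush border, -0.90 for sugar, amino acid and ion transport, -0.39 for lipid absorption, 0.39 for cholesterol synthesis, -0.27 for trophic factors, -0.79 for T and NK cells and -0.67 for interferon and antigen presentation; 0 of the 7 lists held with an estimated correlation.

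Pancreatic transcripts in the jejunal array of rat 36 were argued against as the source of these differences, since 14 of 18 probes kept their direction and call without that rat. A sham jejunal sample taken nearer the ileum than the SBS ones may account for part of them. Fam151a, Cubn, Cmahp, Slc11a2 and Spink4 stood outside the range of all SBS arrays on the sham jejunal array. A place between the SBS regions does not describe these genes. On an axis from SBS ileum (0) to SBS jejunum (1), with probes chosen on a pair of rats and the axis set by the other pair, the sham jejunal array lay at median positions of 0.392 to 0.677 (24 to 51 probes), and its highest, 0.677, was below 0.8. A resection effect that moves the jejunum away from the ileum gives the same position, and with 1 sham jejunal array these were not separated. A biological difference between the regions in their answer to resection stays open and was not tested apart from them.

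Dixon's ratio is relative to the range of a group, so it also flags small gaps, such as those of Dclk1 and of Fabp6 in SBS ileum below. Of 206 groups of 4 arrays tested for named genes, detected probes and median signal, 15 held an array set apart from the others by this ratio, and chance gives about 1 in 20. In SBS ileum these were Apoe on array 2 (5.86, others 4.70 to 4.72), Cd36 on array 2 (4.85, others 5.60 to 5.69), Hpgds on array 2 (5.03, others 4.37 to 4.43), Cox5a on array 1 (10.30, others 10.37 to 10.38), Guca2a on array 1 (12.32, others 11.54 to 11.63), Fabp6 on array 3 (14.43, others 14.22) and Ndufb5 on array 4 (11.06, others 10.85 to 10.88). In SBS jejunum they were Fabp6 (13.56, others 5.96 to 7.15), Cd36 (5.93, others 7.23 to 7.45), Gsta2 (7.90, others at least 8.97), Dclk1 (4.44, others 4.42) and Pou2f3 (4.42, others 4.28 to 4.29) on array 4, Abcg2 on array 1 (10.62, others 10.06 to 10.14), and Cmahp (5.29, others 5.95 to 6.02) and Ndufb5 (11.29, others 11.25) on array 2.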

How the results depend on the processing

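The fit without rat 36 and the settings for lists on region and on the difference of effects were chosen after seeing the data. Other settings kept 2027 results for named genes and 286 for lists on the same side of the threshold, weakened 165 and 32, and strengthened 41 gene results; the cause was not tested where none is given. Of probes called in ileum (269), array weights gave 930, no filter (more probes tested) 171 and the fit without rat 36 (fewer arrays) 140. Of those in jejunum (134), median scaling gave 80, no filter 72, array weights 244 and the 5 jejunal arrays alone (fewer arrays) 21. For the difference of effects (18), array weights gave 51 and the animal as a random block 36, and for region (849) the random block gave 1519. With quantile normalization and with median scaling, the median difference of all probes was 0.03 and -0.09 in ileum and -0.01 and 0.16 for the difference of effects. Median scaling moved the share of higher probes from 22.3% to 9.01% in ileum, 43.3% to 62.5% in jejunum and 52.8% to 67.8% between regions. With an estimated correlation 0 lists were called in ileum, 0 in jejunum, 0 for the difference of effects and 0 between regions, and fry called 1, 3, 0 and 10. Array weights left 4 lists for the difference of effects.

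Sham and SBS ileal arrays share only a number; their deviations correlated by 0.21, -0.08 and 0.03, and not every array correlated best with its own number. With the replicate block 787 probes were called in ileum and 377 in jejunum, 23 and 4 lists for the difference of effects, and the PDGF median in jejunum was -0.42. For the same rats' regions, the block gave 1270 probes over all arrays and 1273 over the SBS arrays. With the block calls were lost in jejunum brush border and S100g, and for the difference of effects brush border, transport, lipid absorption, trophic factors, Bok and Slc5a12.

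The PDGF median in jejunum (-0.68) was -0.0447 with no filter, where dim genes enter, and -0.57 with the random block; 2 genes were measured after the filter, too few for a list call. The Pdgfa difference between regions reversed to 0.139 with median scaling, 0.0634 with cyclic loess, 0.142 without SBS ileum 1 and 0.0931 without SBS jejunum 2, and in ileum to 0.0935 without sham ileum 1 and 0.00608 without SBS ileum 2. With each array left out in turn, counts ran from 26 to 331 in ileum, 98 to 174 in jejunum, 8 to 28 for the difference of effects and 594 to 930 between regions, and lists from 3 to 7, 6 to 8, 5 to 10 and 7 to 8. The PDGF median ran from -0.237 to 0.0411 in ileum and -0.76 to -0.65 in jejunum, and Pdgfa from -0.304 to 0.0935 in ileum and -0.182 to 0.142 between regions. A chip block was not run, since chips are not given. Dim genes near the background are limited by signal.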

Other observations

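The tests of T and NK cells, of follicle genes and of both muscle lists were chosen after the result was seen. In jejunum the 4 measured blood genes had a median of -1.40 after resection (adjusted p = 0.0867), and 3 fell when adjusted over the list alone; 3 B and plasma cell genes fell when adjusted over the list alone (median -1.57) and 0 over all probes. Paneth cell and antimicrobial genes in jejunum had a median of -0.14 against a mean of 0.45 (adjusted p = 0.959). Other pancreatic genes on SBS jejunum 1 stood at 7.12 (Cela2a), 6.55 (Prss1), 6.45 (Cpb1) and 6.23 (Cpa1), against at most 4.58, 4.57, 4.47 and 4.86 elsewhere.

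Other splits of the samples were counted. Of 35 splits of the 7 ileal arrays 1, the real one, gave as many called probes (269, highest other 74), while 20 gave as many called lists (5, highest other 13). With only 35 splits, chance was made less likely for the count of probes but was not excluded. For the lists chance cannot be excluded. Of 35 splits of the 8 SBS arrays 1, the real one, gave as many probes (849, highest other 212, the split of rats 36 and 38 from 37 and 39), and 8 gave as many lists (7, highest other 13). Among the 8 splits that part all pairs, the highest other counts were 0 probes and 7 lists.

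Lower B cell markers in resected ileum were weighed against a change common to probes of the same brightness. The 2132 probes within 0.25 of their sham levels had a median of 0.0153. Quantile normalization gives every array the same distribution and largely removes such a change, so this test cannot decide on it. Fewer immune cells of all kinds were weighed with T and NK markers, with a median of -0.00021 (-0.53 to 1.30 over 12 genes). Of these, 6 differences were positive and 6 negative. The T cell gene Cd3d stood at 7.14 to 8.27 in sham and 6.52 to 7.80 in SBS ileum, and the granzyme gene Gzmb at 6.15 to 7.51 and 7.73 to 8.32. The median argues only against a fall common to all T and NK genes, and fewer T cells were not excluded. These values cover T and NK cells only. The 7 measured macrophage and dendritic cell genes had a median of -0.54, with 3 positive and 4 negative differences and 0 passing (adjusted p = 0.627 in camera). A fall of those cells was not excluded. More lymphoid follicle in the sham samples may account for the pattern: Ms4a1, Cd79b, Cr2 and Cxcl13 correlated within groups by 0.904 on average (Spearman 0.897, one-sided permutation p = 0.00015 for Pearson and 0.00002 for Spearman with 100000 permutations), above 100% of 10000 random sets, and by 0.824 without 2 arrays. Such genes go together whatever lowers them, so the correlation cannot tell sampling from resection. Clu, Mfge8, Enpp2, Prkcb, Cd83 and Apoe were, like Cxcl13, lowest on sham ileum 1 and highest on SBS ileum 2 within their groups. The same limit may hold for their falls in ileum, which was not tested. On the lone sham jejunal array Cxcl13 stood at 7.82 and Cd79b at 6.77, above the SBS jejunal arrays (4.46 to 5.71 and 4.72 to 4.94). Whether the sampled piece or the resection set the amount of follicle was not tested, and the effect of resection stays open.

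Higher Acta1 in resected rats was weighed against muscle in the samples. Of 13 other skeletal muscle genes on the array 9 were detected on 0 arrays, and the median log2 difference in ileum was 0.00128 (-0.23 to 0.14 over the 13 genes), which argues against skeletal muscle. Smooth muscle genes had a median of -0.36 (-0.83 to 0.07 over 6 genes), which argues against muscle of the gut wall. The upper quartiles of the differences were 0.0331 and 0.0188, and the tests as run asked that these lie under 1, which is stricter than the median. Acta1 stood at 5.51 on the sham jejunal array and 8.60 in SBS jejunum, and a biological explanation was not tested.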
